A study of Arabidopsis thaliana with 2 samples.

How the data were processed

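Leaf chromatin of 1 wild-type and 1 chr5 mutant sample was digested with MNase and the protected DNA was made into standard genomic libraries, per the labels' protocols. The submitters' processing notes name BWA 0.7.5a and bedtools; their roles, the handling of duplicates and of reads with several matches, whether reads or fragments were counted, and the genome build are not given in the sources used here. The authors deposited 1 table per library with whole-number counts in consecutive bins of 10 kb over 5 nuclear chromosomes, the chloroplast and the mitochondria. The deposited counts are not normalized: they sum to 99909809 in the wild type and 102961878 in the mutant. In both libraries, 5 of the 16 chloroplast bins, from 90001 to 110000 and from 130001 to 154478, hold 0 counts, as do 66 nuclear bins, 24 of which overlap a protein-coding gene. A bin of 0 allows up to 3 counts (0.030 per 1000000 nuclear counts in the wild type) and may reflect how the reads were filtered, so such bins were not read as free of nucleosomes.

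Genes were placed with a RefSeq gene table of assembly TAIR10.1, whose coordinates are not printed; bin coordinates are those of the deposited tables, counted from 1. Because no build is named, the placement was checked on the data. In each of 10 segments, from splitting each of the 5 chromosomes at its middle bin, the correlation across bins of the wild-type log2 count with protein-coding coverage, both less their running median of 21 bins, was highest with no shift (0.24 to 0.72), against at most 0.14 at shifts of 1 to 4 bins either way. All last genes lay within the chromosome lengths of the tables. The placement of genes rests on this check. All members of the fixed gene lists were matched by locus ID, and symbols are those of the table. No genome sequence was used here, so GC content was not computed.

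Counts were scaled to the total of each library in nuclear bins. The log2 ratio of mutant to wild type used a pseudocount of 1 added to each count. Bins with a mean scaled count under 0.25 times the nuclear median were left out, which removed 181 of 11916 bins. The median analysed bin held 7978 counts in the wild type and 8296 in the mutant, and the smallest wild-type count was 1798. Folds of single bins come from the counts without a pseudocount, with exact conditional binomial intervals at 95%, and shares have exact Clopper-Pearson intervals; both cover counting error only, and reads are not independent molecules when PCR copies are kept.

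The design, the alternatives, the gene lists and regions and the rule for named genes were fixed before the data were examined. The named items were the CHR5 bins, the 12 highest and 12 lowest analysed bins with up to 2 genes that cover most of each, and the 2 highest and 2 lowest members of each gene list, with SNC1, ABI3 and FUS3 in any case; 1 item that this rule names is not reported here. FLC, RPP5, LHCB2.1, RCA, RBCS3B, the most counted rRNA bins and a bin next to the highest and to the lowest one were added after their values were seen. The pericentromeres were bins within 2 Mb of approximate centromere positions (15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5). The centromere cores reached 0.5 Mb, the knob of chromosome 4 ran from 1.6 to 2.3 Mb, the mitochondrial insertion of chromosome 2 from 3.2 to 3.5 Mb, the chromosome ends were 100 kb and the nucleolus organizer ends 20 kb long. Region differences were placed among 10000 rotations of the labels along the genome, which keep neighbouring bins together. A gene was assigned to the bin of its midpoint. List medians were placed among 10000 random bin lists of the same size matched on mean count in 20 classes. With other filters and for all bins that a gene overlaps, the rotations and lists were redrawn, a comparison chosen after seeing the data. These percentiles describe the 2 libraries and are no test between genotypes. The gene table names no class of transposable element genes, so the annotated pseudogenes were used as a class added after seeing the data.

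Scripts were tested on simulated Poisson counts with the means and depths of the real bins. Of 200 bins changed by 1.7-fold among 11916, 100% of the raised and 100% of the lowered ones passed 1.5-fold, with 0 unchanged bins past it. A pericentromeric shift set to -0.1 was found as -0.10. The simulated counts carried counting error only, whereas the log2 ratio of the real bins had an SD of 0.064 against 0.024 from counting. The simulation therefore tests the scripts and gives no rate of false bins for these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The alternatives were a median-based scaling, totals that include organelles, no filter or a stricter one, a pseudocount of 10, other thresholds, bins of 50 kb, other widths of the pericentromere and another assignment of genes to bins.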

Results

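The series profiled nucleosome-protected DNA in Arabidopsis thaliana leaves by MNase-seq, in which chromatin is digested with micrococcal nuclease and the DNA that survives is sequenced. It holds 1 wild-type library and 1 library of the chr5 mutant, both from plants grown on plates at 22 °C without treatment. CHR5 (AT2G13370) encodes a SNF2-family chromatin remodelling protein of the CHD1 type, and the comparison asks how nucleosome-protected DNA is distributed over the genome when it is mutated. The wild-type library held 99909809 counts and the mutant library 102961878 counts in bins of 10 kb. A bin of this size spans many nucleosomes and usually several genes, so each value below belongs to a bin and not to a nucleosome or to a gene alone. With 1 library per genotype no difference has a replicate check, no test between genotypes was possible, and the intervals of folds and shares cover counting error only. The block bootstrap ranges given further below cover variation among stretches of the genome within these 2 libraries, not between preparations. All folds are mutant over wild type after scaling each library to its total in the 5 nuclear chromosomes, which was 99392770 counts in the wild type and 102412872 in the mutant.

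At the CHR5 locus the mutant library was close to the wild type. The 2 bins that hold the gene (chromosome 2, 5540001 to 5560000) had 15526 counts in the wild type and 15636 in the mutant, a fold of 0.977 (exact 95% interval 0.956 to 0.999). Both bins are pericentromeric, where the median log2 ratio was -0.054, and theirs together was -0.033. The allele is not given in the labels, and a bin of 10 kb cannot check an insertion or a point mutation, so these counts say nothing about the label.

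The 2 genome-wide profiles were nearly alike. Across the 11735 nuclear bins that passed the count filter, Pearson's r of the log2 counts was 0.993 and Spearman's rho was 0.993. These are correlations across bins, and bins are not independent replicates. The median log2 ratio was 0.015 with an SD of 0.064 over bins, against an SD of 0.024 from Poisson counting alone. The central 95% of bins lay between folds of 0.907 and 1.08. At a threshold of 1.5-fold, 1 bin was higher and 1 bin was lower in the mutant, against 5 and 6 when bins with few counts were not filtered out. At the lower threshold of a 25% change, taken as the same fold either way, 2 bins were higher and 21 were lower, and 18 of these 21 lay in the pericentromeres, which hold 16.0% of the analysed bins. The lowest bin was down by 42.1%, so no analysed bin was lost from the mutant library.

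The ratio of mutant to wild-type counts was lower in the pericentromeres than in the chromosome arms. The median log2 ratio was -0.054 over the 1882 pericentromeric bins (within 2 Mb of the approximate centromere position) and 0.021 over the 9853 arm bins, a difference of -0.075, or 0.949-fold. The spread over bins was an SD of 0.084 in the pericentromeres and 0.050 in the arms. In the pericentromeres 77.1% of bins were below 0, against 31.2% in the arms. The difference had the same sign on each chromosome: -0.067 on chromosome 1, -0.070 on chromosome 2, -0.073 on chromosome 3, -0.084 on chromosome 4 and -0.087 on chromosome 5. When the region labels were rotated along the genome, the observed difference lay at percentile 0.065 of 10000 rotations.

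Of the 5 smaller regions fixed in advance, the centromere cores and the insertion of mitochondrial DNA lay below the central 95% of the rotations and the other 3 lay inside it. These regions overlap. The cores lie within the pericentromeres, the insertion within the core of chromosome 2, and part of the knob within the pericentromere of chromosome 4. Their places are therefore not separate from the pericentromere result. The centromere cores (within 0.5 Mb, 416 bins) were at -0.091 relative to all other bins, at percentile 0.165 of the rotations. The heterochromatic knob of chromosome 4 (70 bins) was at -0.085, at percentile 4.38. The insertion of mitochondrial DNA on chromosome 2 was at -0.11, at percentile 1.54, with 17 of its 30 bins passing the count filter. This place depended on the filter: with rotations redrawn, the insertion was at -0.091 with no filter (percentile 3.04) and at -0.098 with the filter at 0.5 and 4 times the median (percentile 2.995, 7 bins), inside the central 95% both times, while the cores stayed below it. The chromosome ends (100 bins) were at -0.019, at percentile 9.40, and the 4 bins at the nucleolus organizer ends of chromosomes 2 and 4 were at -0.021, at percentile 28.1. Under the filter at 0.5 and 4 times the median, 2 of these 4 bins were left, at -0.048 and percentile 11.9. The bins of rRNA genes, which were among the 3 with the most counts, had ratios close to 1. The bin of the rRNA gene AT3G41768 (chromosome 3, 14190001 to 14200000) had 946140 counts in the wild type and 983701 in the mutant, a fold of 1.009 (1.006 to 1.012), and the bin of AT2G01010 (chromosome 2, 1 to 10000) had 513687 and 539213, a fold of 1.019 (1.015 to 1.023). The median of the 2 rRNA bins was 0.020, at percentile 97.7 of random bins from their class of mean count. Only 8 bins exceeded 10 times the median count, so that class held mostly bins with far fewer counts. This percentile therefore does not compare the rRNA bins with bins of the same count, and nothing was concluded from it. The 464 bins with tRNA genes had a median of 0.018, at percentile 64.2 of random bin lists matched on count.

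**Figure D1:**
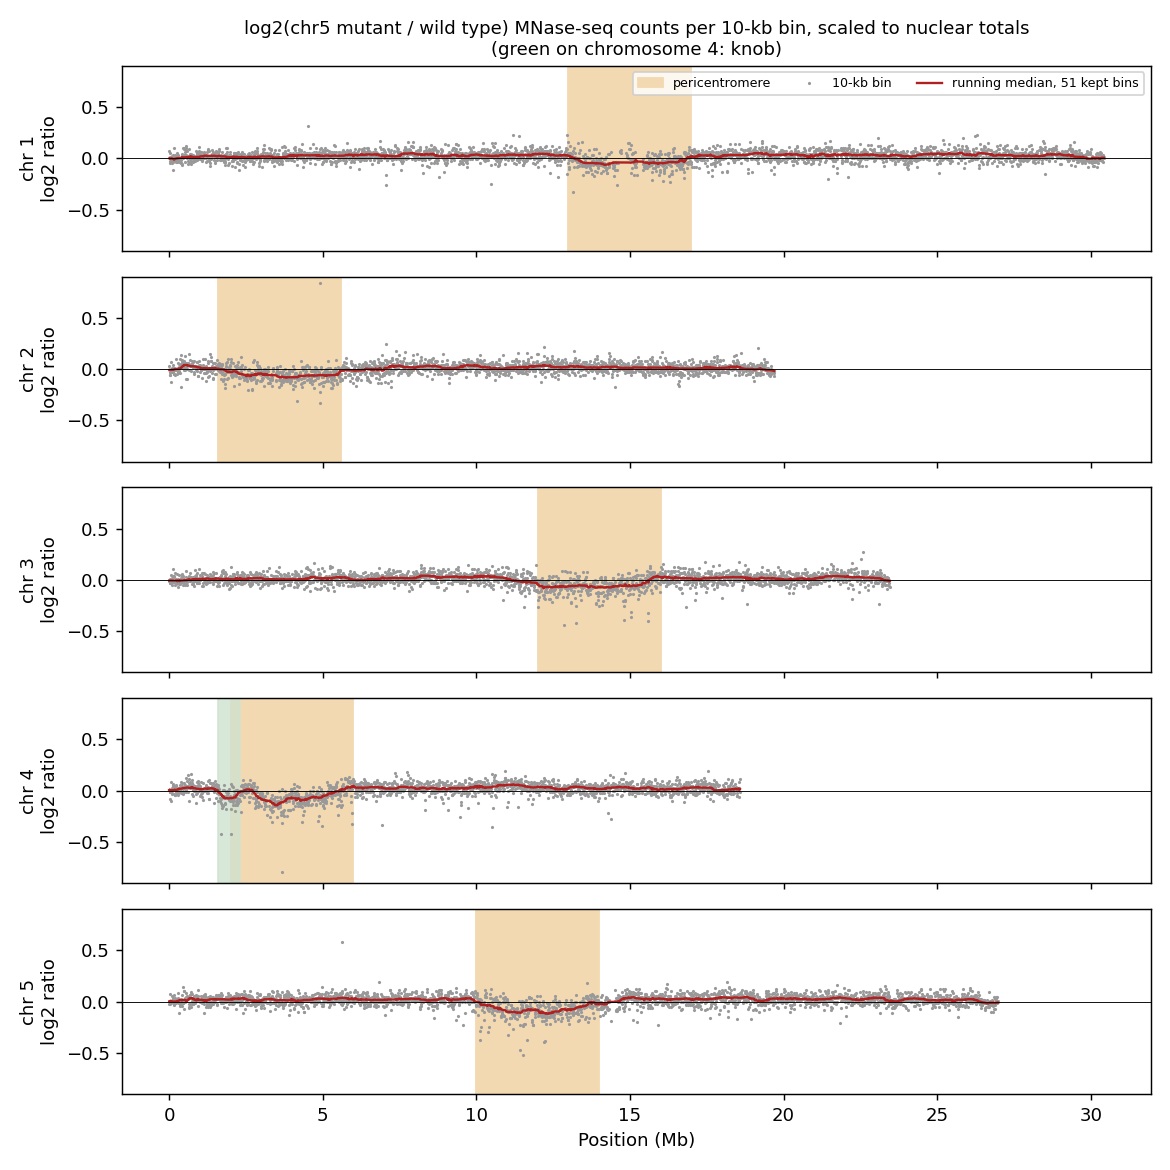
Log2 ratio of mutant to wild-type counts (y axis) against position in Mb (x axis) for the analysed 10-kb bins of the 5 nuclear chromosomes; grey points are bins, the red line is a running median of 51 bins, orange marks the pericentromeres and green the knob of chromosome 4. The line dips below 0 over most of the orange regions, whose median is -0.054, and in the knob, whose median is -0.070. The arm median is 0.021.

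The pericentromeric difference was concentrated in gene-poor bins. Among bins with under 25% of their length in protein-coding genes, the 1477 pericentromeric bins were at -0.066 and the 869 arm bins at 0.020. Among bins with over 75% the medians were 0.016 for 36 pericentromeric bins and 0.011 for 3565 arm bins. Over all analysed bins the log2 ratio had a Spearman's rho of 0.12 with protein-coding coverage and of -0.39 with coverage by annotated pseudogenes. It also had a rho of -0.43 with the mean count of the bin, so bins with few counts tended to be higher in the mutant. The medians of all bins ran from 0.052 in the lowest decile of mean count to -0.046 in the highest. Pericentromeric bins were below arm bins in all 10 deciles, by a median of -0.061.

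**Figure D2:**
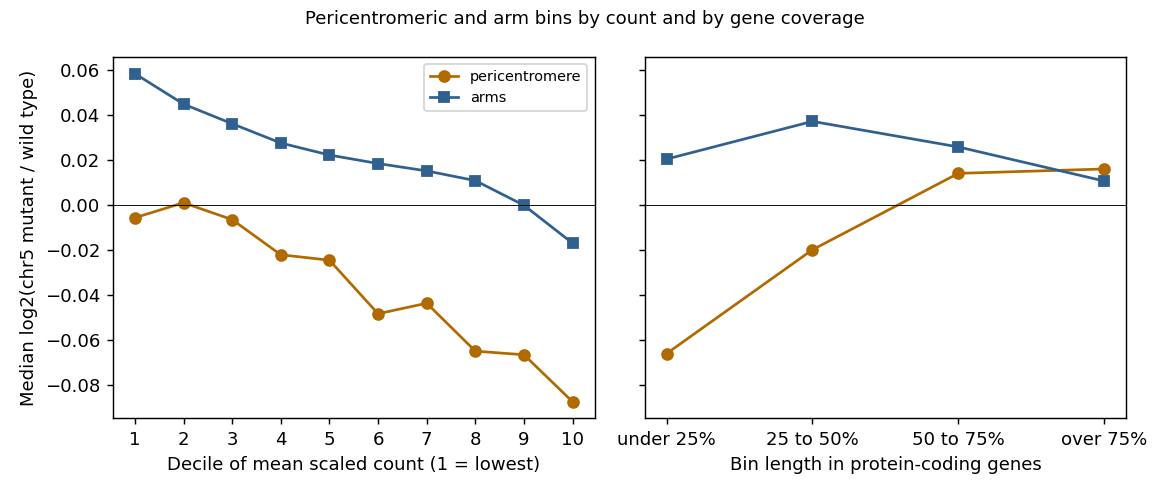
Median log2 ratio of mutant to wild type (y axis) for pericentromeric bins (circles) and arm bins (squares), by decile of mean scaled count (left x axis) and by the share of the bin in protein-coding genes (right x axis). Circles lie below squares in all 10 deciles of count, and meet them in bins with over 75% coverage, at 0.016 and 0.011.

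The 12 lowest bins were stretches of annotated pseudogenes with high counts. Of these bins, 11 lay in the pericentromeres and 2 in the knob of chromosome 4, of which 1 lay in both, and a median of 63.0% of their length was annotated pseudogene. The lowest was on chromosome 4 (3680001 to 3690000, pseudogenes AT4G06604 and AT4G06603), with 15161 counts in the wild type and 9050 in the mutant, a fold of 0.579 (0.564 to 0.595), and the bin before it (3670001 to 3680000) went the same way, at 0.803 (0.780 to 0.826). Next were 2 bins on chromosome 5, at 11500001 to 11510000 (AT5G31355 and AT5G30410) with a fold of 0.698 (0.681 to 0.714) and at 11430001 to 11440000 (AT5G31662 and AT5G31752) with a fold of 0.724 (0.707 to 0.740). On chromosome 3, the bin of AT3G31530 was at 0.739 and that of AT3G32295 at 0.746. In the knob, the bins of AT4G04157 and of AT4G03770 were both at 0.749. The other 5, led by AT3G43681, AT5G32540, AT3G42727, AT5G32598 and AT5G28100, ranged up to 0.771.

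The 12 highest bins were mostly arm bins with few counts, and 11 of them were below the median wild-type count. Their median protein-coding coverage was 10.2%, so many of them hold little of the genes named below. The highest was pericentromeric, on chromosome 2 (4900001 to 4910000, pseudogene AT2G12210 and the protein-coding AT2G12200), with 11602 counts in the wild type and 21294 in the mutant, a fold of 1.78 (1.74 to 1.82). The bin next to it (4910001 to 4920000) went the other way, with 4728 and 3865 counts and a fold of 0.793 (0.760 to 0.828). The second was on the arm of chromosome 5 (5630001 to 5640000, pseudogene AT5G17125 and AT5G17150), with 4668 and 7175 counts and a fold of 1.49 (1.44 to 1.55). The remaining 10 lay between log2 ratios of 0.21 and 0.32. They include the bin that reaches GATL3 (AT1G13250, a galacturonosyltransferase-like gene), at a log2 ratio of 0.32 with 1798 wild-type and 2310 mutant counts, and the bin of AT3G61030 at 1.21 (1.14 to 1.29). The bin of KCS9 (AT2G16280), a ketoacyl-CoA synthase gene of fatty acid elongation, was at 1.19 (1.14 to 1.23). That of the nitrate transporter gene NRT1:2 (AT1G69850), with 10.6% protein-coding coverage, was at 1.17 (1.11 to 1.23). One bin that reaches into CMT3 (AT1G69770), which encodes a DNA methyltransferase of CHG sites, was at 1.16 (1.10 to 1.22), and that of MIR166a (AT2G46685) at 1.16 (1.10 to 1.22). A bin with 9.81% protein-coding coverage that reaches VHA-A1 (AT2G28520), a proton pump subunit gene, was at 1.16 (1.10 to 1.22). The bins led by AT1G35280 and AT1G31310 were both at 1.17, and 1 bin at 1.16 held no annotated gene.

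Bins of photosynthesis genes had the lowest median ratio of mutant to wild type among the 8 gene lists fixed in advance. Of the 10 bins that hold the 13 genes, 9 were below the genome median, and the list median was -0.036 (-0.051 with the median bin set to 0). The bin of CAB1, CAB2 and CAB3 (AT1G29930, AT1G29920 and AT1G29910), which encode chlorophyll-binding proteins of the light-harvesting antenna, was at a fold of 0.843 (0.819 to 0.868), with 9882 wild-type and 8582 mutant counts. That of LHCB2.1 (AT2G05100), another antenna gene, was at 0.881 (0.850 to 0.913) and that of RCA (AT2G39730), the Rubisco activase gene, at 0.907 (0.882 to 0.934). The highest were the 2 bins of the Rubisco small subunit cluster, with a log2 ratio of 0.0012 for RBCS3B and of 0.047 for RBCS2B and RBCS1B. The list median lay at percentile 0.10 of 10000 random bin lists matched on count, and at percentile 0.020 of random lists of protein-coding genes, a comparison chosen after seeing the data. CAB1 to CAB3, and the RBCS genes, are near-identical copies whose reads the counting could split between copies or leave out. Without the bin of CAB1 to CAB3 the median was -0.023 (percentile 0.17 of random gene lists), and without that of LHCB2.1 as well it was -0.020 (0.45). Without these and the bins of all RBCS genes, the median of the other 5 bins was -0.049 (0.245).

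Among NLR genes, which encode intracellular immune receptors, 12 of 16 bins were below the genome median and the list median was -0.015, or -0.030 when the median bin was set to 0. The lowest were 2 neighbouring bins of the resistance gene cluster on chromosome 4. The bin of RPP4 (AT4G16860) had 5275 wild-type and 4953 mutant counts, a fold of 0.911 (0.876 to 0.947), and that of SNC1 (AT4G16890) had 8931 and 8520, a fold of 0.926 (0.899 to 0.954). RPP5 (AT4G16950) in the same cluster was at 0.988 (0.952 to 1.03). The highest was AT5G41750 at 1.06 (1.03 to 1.09). The list median lay at percentile 1.78 of random bin lists. With the filter at 0.5 and 4 times the median it was -0.012, at percentile 4.33 of lists redrawn under that filter and so inside their central 95%. Averaged over all bins that each gene overlaps it was -0.0065, at percentile 1.57 of random genes treated alike. Members of this cluster are close copies, so their counts are uncertain; without the bins of RPP4, SNC1 and RPP5 the median was -0.0065, at percentile 4.96 of random gene lists against 0.200 with them.

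The medians of the other 6 lists lay inside the central 95% of random bin lists of the same count. For 21 genes of immune signalling, 16 of 21 bins were above the genome median and the median was 0.037 (0.022 with the median bin set to 0), at percentile 93.0. Its extremes were SAG101 at 1.06 (1.03 to 1.09) and CBP60G at 1.06 (1.02 to 1.10), and RBOHD, the NADPH oxidase gene of the immune oxidative burst, at 0.980 (0.944 to 1.02) and WRKY70 at 0.984 (0.954 to 1.01). For flowering and floral homeotic genes, 11 of 15 bins were above and the median was 0.044 (0.029 with the median bin set to 0), at percentile 92.1. Here the floral organ gene PI (AT5G20240) was at 1.14 (1.11 to 1.18) and the meristem gene STM (AT1G62360) at 1.09 (1.04 to 1.14), while KNAT1 was at 0.980 (0.949 to 1.01) and AP3 at 0.989 (0.961 to 1.02). The flowering repressor gene FLC was at 1.02 (0.992 to 1.05).

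Seed maturation genes were near the genome median, with 9 of 16 bins above it and a list median of 0.018 (0.0033 with the median bin set to 0), at percentile 64.2. The bins of the seed regulators FUS3 (AT3G26790) and ABI3 (AT3G24650) were at 1.05 (1.01 to 1.09) and 1.01 (0.981 to 1.05). The highest were WRI1, a regulator of seed oil synthesis, at 1.06 (1.02 to 1.10) and the storage protein gene CRU2 at 1.05 (1.02 to 1.08), and the lowest were the late embryogenesis genes GEA6 at 0.960 (0.931 to 0.990) and EM1 at 0.964 (0.937 to 0.992). For chromatin remodelling and DNA methylation genes the median was -0.016 (-0.031 with the median bin set to 0), at percentile 19.0. PIE1 was at 0.956 (0.932 to 0.980) and BRM at 0.967 (0.945 to 0.990), and CMT3 by its midpoint bin was at 1.07 (1.03 to 1.11) and MET1 at 1.02 (0.993 to 1.05). The medians of housekeeping genes (0.0062, percentile 24.1) and heat shock genes (0.010, percentile 72.1) turned negative, at -0.0086 and -0.0046, when the median bin was set to 0. Among the former, GAPC1 was at 0.959 (0.933 to 0.986), the elongation factor gene AT5G60390 at 0.974 (0.944 to 1.01), UBC9 at 1.04 (1.01 to 1.08) and PP2AA3 at 1.04 (1.01 to 1.07). Among the latter, HSP18.2 was at 0.948 (0.917 to 0.981), HSFA2 at 0.996 (0.971 to 1.02), HSP70 at 1.04 (1.02 to 1.07) and HSP21 at 1.04 (0.998 to 1.07). In all, these 8 lists and the tRNA and rRNA genes were placed among random bins in this way, as were 5 classes added after seeing the data.

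**Figure D3:**
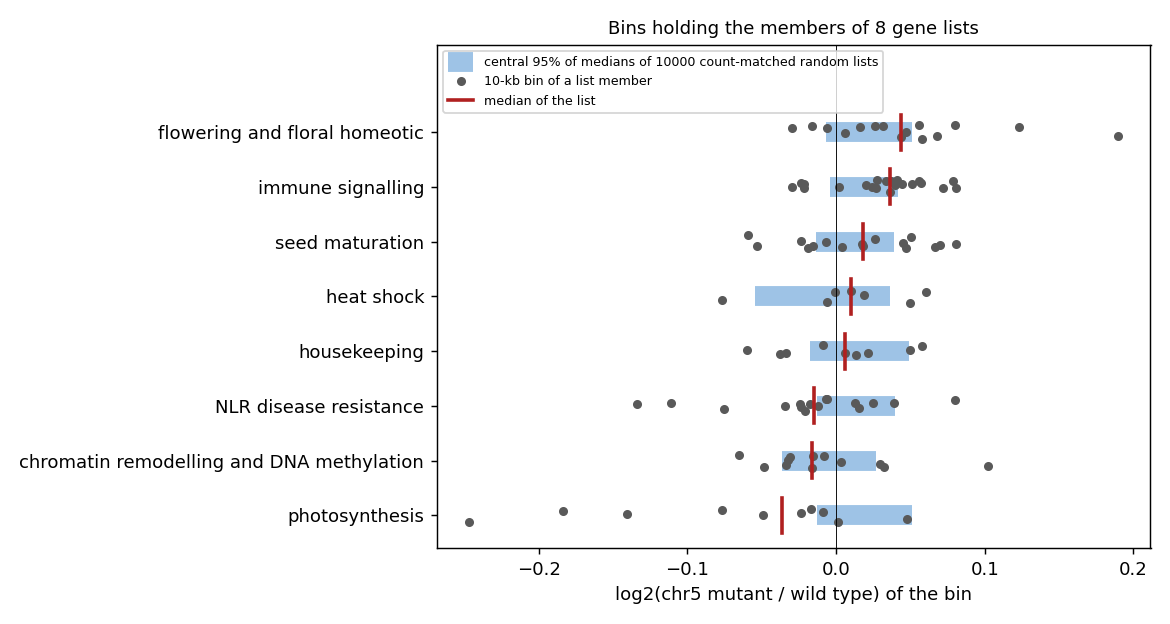
Log2 ratio of mutant to wild type (x axis) of the 10-kb bins that hold members of each of the 8 gene lists (rows); points are bins, red bars the list medians, and blue bars the central 95% of medians of 10000 random bin lists matched on count. The photosynthesis median of -0.036 and the NLR median of -0.015 lie left of their blue bars.

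Organelle DNA was a small part of the counts of both libraries, with 5 of the 16 chloroplast bins at 0 in both. The chloroplast took 0.295% of all counts in the wild type (exact Clopper-Pearson 95% interval 0.294 to 0.297) and 0.317% in the mutant (0.316 to 0.319). The mitochondria took 0.222% (0.221 to 0.223) and 0.216% (0.215 to 0.217). Their counts were uneven, from 25 wild-type counts in the bin 170001 to 180000 to 23528 in the bin 280001 to 290000. The mitochondrial shares therefore rest mostly on the well-covered bins.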

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

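Chloroplast bins entered none of the genotype comparisons over nuclear bins. Per nuclear count, chloroplast counts were 1.07 times as high in the mutant as in the wild type (exact 95% interval 1.07 to 1.08, counting error only), which is above the level in the control library. Mitochondrial counts, which came mostly from the well-covered bins, were at 0.972 (0.966 to 0.978). No cause was examined, and with 1 library per genotype the spread between preparations is unknown.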

How the results depend on the processing

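Of 134 values recomputed under alternatives, 106 stayed within counting error (or, for counts of bins, within 1.5 times), 28 moved further and none of them turned a sign beyond counting error. Some of the 106 could not move. Setting the median bin to 0 or including organelles in the totals shifts all bins alike, which cancels in region differences and in the SD. Apart from the tRNA genes, the fixed lists and the CHR5 locus had no bin below the filter, so dropping it left their values unchanged. The tally is therefore no measure of robustness. The pericentromere difference of -0.075 was -0.072 with no filter, -0.090 and -0.052 with 1 and 3 Mb either side, and -0.067, -0.070, -0.084 and -0.087 on chromosomes 1, 2, 4 and 5 alone. In comparisons chosen after seeing the data it was -0.061 within deciles of count and -0.0032 in bins with at least 50% protein-coding length. The centromere cores moved to -0.080 with no filter and -0.098 with the filter at 0.5 and 4 times the median, under which the nucleolus organizer ends moved to -0.048 and the rRNA bins were removed. The SD of the log2 ratio was 0.071 with no filter, 0.062 with the stricter filter and 0.044 in bins of 50 kb, and the correlation of the libraries was 0.998 and 0.991 under the 2 filters. The 1 higher and 1 lower bin at 1.5-fold became 5 and 6 with no filter, 2 and 21 at a threshold of 25%, and 0 and 0 at 2-fold and in bins of 50 kb. With the median bin set to 0, the immune signalling, tRNA and rRNA medians were 0.022, 0.0035 and 0.0052. Causes of these moves were not tested beyond their construction. The GC correction was not run because no genome sequence was used here. No paired analysis was possible because each genotype has 1 library. Depth does not limit a bin at the median count, where counting alone gives an SD near 0.024, but the spread between preparations is unknown.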

Other observations

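The tests of the count trend, of counting error and of shared reads between gene copies, and the random lists for the non-coding RNA and pseudogene classes, were chosen only after the result was seen.

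Bins of snRNA and of lncRNA genes, classes added after seeing the data, were slightly above bins of the same count. The 73 bins with snRNA genes, whose products act mostly in splicing, had a median log2 ratio of 0.032, at percentile 99.7 of random bin lists matched on count, with 46 bins above the genome median. The 2641 bins with lncRNA genes were at 0.024, above all 10000 random lists, whose central 95% ran from 0.017 to 0.021. The random lists were matched on count but not on position, and the median of all arm bins was 0.021. The places of these classes therefore do not separate the class of gene from position in the arms. The 140 bins with snoRNA genes, at 0.024 (percentile 94.6), and the 293 bins with miRNA genes, at 0.026 (percentile 83.2), lay inside the central 95% of random lists. The 784 bins with at least 50% annotated pseudogene were at -0.076, against -0.016 for random lists, with 720 bins below the genome median.

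Of the 10 bins with the most counts, 1 lay outside the pericentromeres and the nucleolus organizer ends. This bin, at 3250001 to 3260000 on chromosome 5 with AT5G10350 and AT5G10340, had 159815 counts in the wild type and 172987 in the mutant, 19.0 and 19.4 times the median of its neighbours. The 8 bins above 10 times the median count took 3.16% of nuclear counts in the wild type and 3.21% in the mutant. The SD of log2 counts over arm bins was 0.468 in the wild type and 0.450 in the mutant.

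The first pattern weighed is the lower ratio of mutant to wild type in pericentromeric bins than in arm bins. A trend of the ratio with the count of a bin is argued against as the whole cause, since the difference stayed at a median of -0.061 over the 10 deciles of count. Pseudogene content followed the pattern. The 136 arm bins outside the knob with at least 50% pseudogene lay at -0.060 relative to count-matched arm bins without any (block bootstrap 95% range -0.078 to -0.047). Against the same reference, 281 pericentromeric bins without annotated pseudogenes lay at -0.018 (-0.030 to -0.0090). This remainder met the bound set before the comparison for pseudogene content rather than position. The bound lies inside the bootstrap range, however, and the class was chosen after seeing the data, so the comparison does not decide between them. The 631 pericentromeric bins with at least 50% pseudogene lay lowest, at -0.084 (-0.092 to -0.075). As a hypothesis, the difference may go with the repeat-like sequence content of heterochromatin. The arm bins were matched on count but not on distance from the centromere, so closeness to it was not separated from content. For the remaining -0.018, position and repeats that the gene table does not name cannot be told apart either. A different degree of MNase digestion cannot be told apart from the genotype, because each genotype was digested once; a tilt with gene coverage was present among arm bins too (rho -0.19), opposite in sign to the rho of 0.41 in the pericentromeres, and GC content and fragment lengths were not used here.

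The second pattern is the 3 bins that stood far from the others, on chromosomes 2 and 5 (higher) and 4 (lower). Counting error alone is argued against, as the interval bound closest to 1, as a fold either way, was 1.44 (chromosome 5). On chromosome 2 the bin was at 1.27 times the median of its neighbours in the wild type and 2.3 times in the mutant. On chromosome 5 the values were 0.541 and 0.790, and on chromosome 4 they were 1.22 and 0.811. Ordinary bins vary too: over arm bins the log2 counts had an SD of 0.468 in the wild type and 0.450 in the mutant. These values therefore do not show whether 1 or both libraries departed from the neighbours. A bin beside the one on chromosome 2 went the other way (0.793) and one beside that on chromosome 4 the same way (0.803). A copy change in 1 stock and a change of occupancy cannot be told apart for these bins, because no undigested DNA was analysed here.

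The third pattern is the lower ratio of mutant to wild type in the bins of photosynthesis genes. Reads shared among the CAB, LHCB2.1 and RBCS copies are argued against as the whole cause, since the 5 bins left without these genes had a median of -0.049, below the central 95% of random gene lists (-0.023 to 0.056). Without the CAB and LHCB2.1 bins alone the list median was -0.020, also below theirs (-0.0083 to 0.056). The further fall to -0.049 came from leaving out the RBCS bins, which include the highest of the list. Copies of the other genes were not searched for by sequence. The genotype, the degree of digestion and other differences between the 2 plant preparations stay open, since each genotype has 1 library.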
